A study of Homo sapiens with 6 samples.

How the data were processed

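Gene expression was measured in LX-2, an immortalised line of human hepatic stellate cells, on 6 Affymetrix 3′ expression arrays. Per the labels' protocols, cells were kept without serum for 12 h and then given recombinant human BMP9 at 0 or 50 ng/ml for 24 h. Total RNA was amplified and biotin-labelled with a 3′ in vitro transcription kit, per the labels' protocols, and each sample was hybridised to 1 array. The labels call the 3 samples of each group biological replicates and say no more about separate cultures, so the p-values measure the spread between these samples. The number of arrays limits the precision, and the table holds no detection calls.

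The deposited values are log2 expression values per probe set, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA's software, version and settings are not given in the sources used here. The log base is not stated either and was taken from RMA's usual output and from the range of the values. RMA subtracts background, normalises the arrays by quantiles at the probe level and summarises the probes of each probe set, so a change shared by most transcripts is largely removed. The table held 49395 probe sets. Of these, 102 were array controls, 44988 carried 1 gene symbol, 1832 carried several and 2473 carried none in the platform's annotation. Through their Entrez identifiers, 44961 of the single-gene probe sets matched a current gene in the gene table of assembly GRCh38.p14, used for names and gene lengths, and 0 symbols changed. All 6 columns were matched to samples by their identifiers. No pair of arrays held the same values: at most 0.00405% of the values were identical between 2 arrays.

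Each gene was represented by its single-gene probe set with the highest mean log2 value over the 6 arrays, which gave 18132 genes, 11734 of them with more than 1 probe set. No filter on dim probe sets was applied, and probe sets with several symbols or none were kept out of the gene comparison. BMP9 was compared with control in limma 3.58.1 (lmFit and eBayes, constant prior, no covariate) under R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 6.13 degrees of freedom beside 4 residual ones, and the median standard error of a log2 difference was 0.0875. Differences are BMP9 minus control, with limma's moderated standard error (SE), and group values are means ± SD over 3 arrays. Summaries per array were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. Figures were drawn with matplotlib 3.10.9.

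Gene lists were written from textbook knowledge, 31 in all: BMP-SMAD1/5/9 direct targets, BMP9 receptors and BMP signal transduction, TGF-beta/BMP family ligands, TGF-beta-SMAD2/3 targets, collagens, collagen maturation and cross-linking, non-collagen matrix, matrix proteases and inhibitors, myofibroblast contractile genes, quiescent stellate cell genes, stellate activation receptors, YAP/TAZ targets, Notch pathway, osteogenic and chondrogenic genes, NF-kB and inflammatory cytokines, interferon-stimulated genes, S phase, G2/M, cell cycle inhibitors and p53 targets, cholesterol synthesis, fatty acid synthesis and lipid storage, glycolysis and hypoxia, unfolded protein response, NRF2 targets, immediate early genes, angiogenic factors, epithelial-mesenchymal regulators, and markers of hepatocytes, endothelial cells, macrophages and leukocytes, and cholangiocytes. They named 518 members, of which 493 were measured. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and beside it with an estimated correlation and with fry. fry asks whether a list's genes move, on balance, in a single direction, without comparing them with other genes.

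The grouping, the tests, the lists, the rule for naming genes and all but 4 of the alternatives were fixed before the data were examined. The rule named the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, all arrays of a group on the same side of the other group and a mean log2 value of at least 6 in the higher group. It also named up to 4 members of each list with the smallest p, and always GDF2, ACVRL1, BMPR2, ENG, ID1, ID2, ID3, SMAD6, SMAD7, HAMP, ACTA2, COL1A1, COL1A2, TIMP1 and TGFB1; 1 further gene of the rule is not reported here. Genes without a plain symbol were passed over, and genes named outside the rule are said to be so.

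The alternatives chosen in advance were the replicate number as a block, quantile normalisation on top of the deposited values, centring each array on its median, a minimum mean log2 value of 5 or 7, the mean over a gene's probe sets, every probe set tested on its own, an intensity trend with a robust prior, a fold minimum of 1.5, Welch's test per gene, each array left out in turn, and the other list tests. The 4 alternatives chosen after seeing the data scaled each array to its hybridisation controls or to its poly-A controls, combined a gene's probe sets by Simes' method, or left out probe sets with the suffixes that mark probes shared with other transcripts. Hybridisation controls are bacterial and phage transcripts that the kit's maker supplies already labelled, and poly-A controls are bacterial transcripts meant to be added to total RNA before labelling; how they were added here is not given in the sources used here. The fits were tested on simulated data with the real genes' means and limma's prior spread. Of 100 genes changed by 1 on the log2 scale, 100% were recovered, and of 100 changed by 0.5, 61%, with 5 false calls among the unchanged genes and 0 calls in a data set without changes. In a set of lists with 1 list shifted by 0.5, camera called that list and 1 other. The simulated genes varied independently of each other, so these checks do not cover correlation between the members of a list.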

Results

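The series asked how recombinant human BMP9 affects LX-2 cells. Hepatic stellate cells are the vitamin A-storing cells of the liver that turn into matrix-producing myofibroblasts in fibrosis, and LX-2 is a human line derived from them. BMP9, the product of GDF2, is a ligand of the TGF-beta family that signals through the receptors ACVRL1 and BMPR2 and through SMAD1/5/9. After 12 h without serum, 3 samples received 50 ng/ml BMP9 and 3 received 0 ng/ml (control) for 24 h, and each was measured on 1 array. The median log2 value of the arrays lay between 3.55 and 3.57. Pearson's r between arrays, across the chosen probe sets of the 18132 genes, was 0.993 to 0.994 within control, 0.994 to 0.995 within BMP9 and 0.991 to 0.993 between the groups. The first principal component held 35.8% of the variance, with the control arrays between -12.3 and -6.38 and the BMP9 arrays between 8.03 and 12.1.

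BMP9 raised SMAD6, an inhibitory SMAD that restrains BMP signalling, by 3.01 on the log2 scale (SE 0.097), or 8.07-fold, from 5.97 ± 0.17 to 8.99 ± 0.078 (SD, n = 3 arrays per group, limma adjusted p = 3.97e-07). The BMP antagonist GREM1 rose 3.18-fold and ID3, which blocks basic helix-loop-helix transcription factors, rose 3.09-fold. The largest fall under the naming rule was that of EFEMP1, which encodes the matrix glycoprotein fibulin-3 and went from 6.49 ± 0.047 to 4.29 ± 0.28 (SD, n = 3), 4.60-fold lower (limma adjusted p = 2.29e-05). The transcription factor MAF fell 3.70-fold, the collagen gene COL3A1 2.45-fold and the gelatinase gene MMP2 2.36-fold.

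Of 18132 genes tested, 124 changed at a limma adjusted p under 0.05, 42 of them higher and 82 lower with BMP9, and in all 124 the 3 BMP9 arrays lay on the same side of the 3 control arrays. A change of at least 2-fold was seen in 10 risen and 14 fallen genes, and the median absolute log2 difference of the 124 genes was 0.60. Over all genes, 18.8% had groups that did not overlap, against 10% by chance, and the median log2 difference was 0.014. The array's own control probe sets were lower on the BMP9 arrays, and scaling to them changed the split. With arrays scaled to the hybridisation controls, which moved the median of all genes to 0.22, 4502 genes were higher and 75 lower. With scaling to the poly-A controls, which moved it to 0.61, 17425 were higher and 15 lower. All differences below are on the deposited scale, relative to these shifts, and a fall smaller than the poly-A shift turns positive under that scaling. Of the genes below that did not pass on the deposited scale, ID1, SMAD7, HEY1, SNAI2, TGFB1, ACTA2, COL1A2, CTSK, HGF, JUNB, PCNA and EPCAM were called higher with either scaling, and BMPR2, ENG, TIMP1, COL1A1, GDF2, ACVRL1 and HAMP with the poly-A one, the last 3 against a negative difference on the deposited scale.

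**Figure D1:**
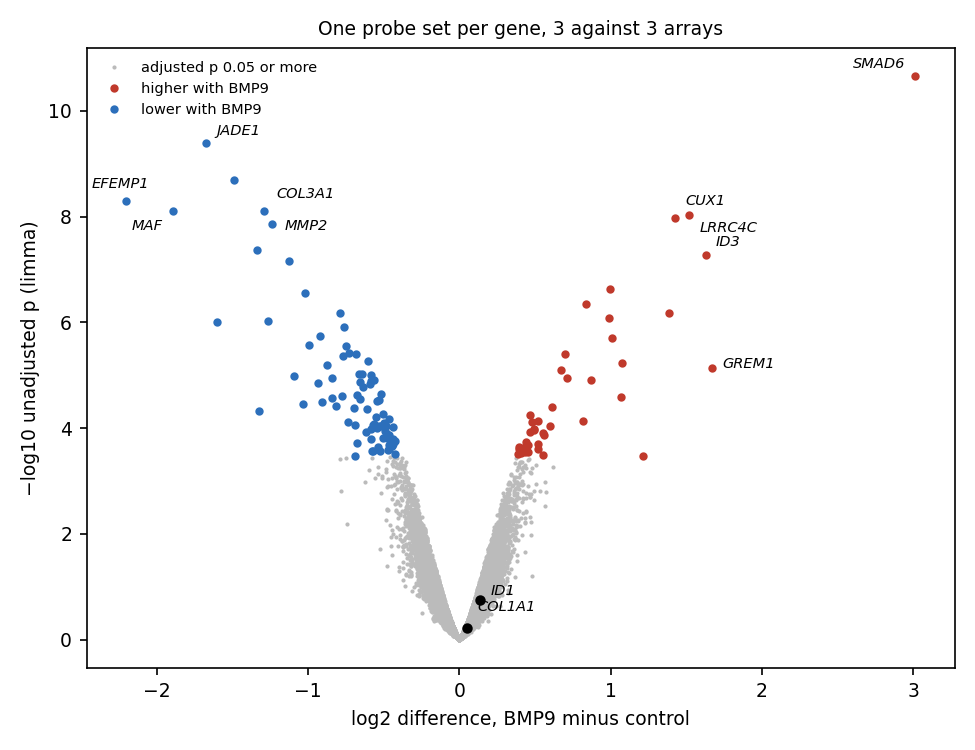
Log2 difference between BMP9 and control (horizontal) against the −log10 of limma's unadjusted p (vertical) for 18132 genes, with genes at an adjusted p under 0.05 in red (42 higher) and blue (82 lower). SMAD6 lies farthest to the right at 3.01 and EFEMP1 farthest to the left at -2.20, while the probe sets chosen for ID1 and COL1A1 (black) lie near 0.

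Among the 10 largest rises under the naming rule, which asks for a mean log2 value of at least 6 in the higher group, LRRC4C, a synaptic adhesion gene with 1 probe set, rose by 1.52 (SE 0.09, limma adjusted p = 2.38e-05), and the homeobox gene CUX1 by 1.42 (SE 0.085). The taurine transporter gene SLC6A6 rose by 1.39, FILIP1L by 1.07, the neuritin gene NRN1 by 1.07, the matricellular gene CCN1 by 1.01 and CXXC5, which encodes a CXXC zinc finger protein, by 0.99 (SE 0.082 to 0.15, limma adjusted p 0.000325 to 0.00919). The other probe sets of a gene did not always move with the chosen one. In CUX1 1 of 4 probe sets passed the test when each was tested on its own, in GREM1 1 of 4, in SLC6A6 2 of 5, in FILIP1L 2 of 7, and in SMAD6 and ID3 2 of 3. The GREM1 probe sets that did not pass stood at 3.1, 2.8 and 1.7 in control and are not known to lie above background. Those of CUX1 stood at 4.86, 4.41 and 3.35. Averaging weighs dim and bright probe sets alike. Averaging all probe sets of a gene ended the calls of GREM1 and FILIP1L, leaving out probe sets with shared probes ended that of FILIP1L, and leaving out control replicate 1 ended that of NRN1.

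The transcription factor gene MAF went from 8.27 ± 0.21 to 6.39 ± 0.10 (SD, n = 3, limma adjusted p = 2.36e-05). JADE1, a scaffold of a histone acetyltransferase complex, fell by 1.67 (SE 0.072, limma adjusted p = 3.70e-06), and the corepressor gene RUNX1T1 fell by 1.49 (SE 0.075). The repressor gene HIC1 fell by 1.09 (SE 0.14), IRF2BPL by 1.02 (SE 0.086) and the zinc finger gene ZNF503 by 0.99 (SE 0.11). CAPN6, a calpain family member, fell by 1.34 (SE 0.093). COL3A1 went from 7.73 ± 0.057 to 6.44 ± 0.063 and MMP2 from 7.82 ± 0.038 to 6.58 ± 0.087 (SD, n = 3). Probe sets differed here too: EFEMP1 passed in 1 of 4, MMP2 in 1 of 4, MAF in 2 of 4, RUNX1T1 in 2 of 5, JADE1 in 3 of 9 and COL3A1 in 3 of 5. Some that did not pass were dim, at 1.97 and 1.78 in control for COL3A1 and at 3.52, 2.54 and 2.20 for EFEMP1. Without detection calls these are not known to lie above background, so they say little against a change. Others were brighter, such as 5.09 in JADE1 and 5.15 in MAF. A second bright probe set of MMP2 differed by -0.08 (7.10 ± 0.11 in control and 7.02 ± 0.31 with BMP9, SD, n = 3). Averaging probe sets ended the calls of MMP2, HIC1 and ZNF503, and leaving out probe sets with shared probes ended that of IRF2BPL.

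**Figure D2:**
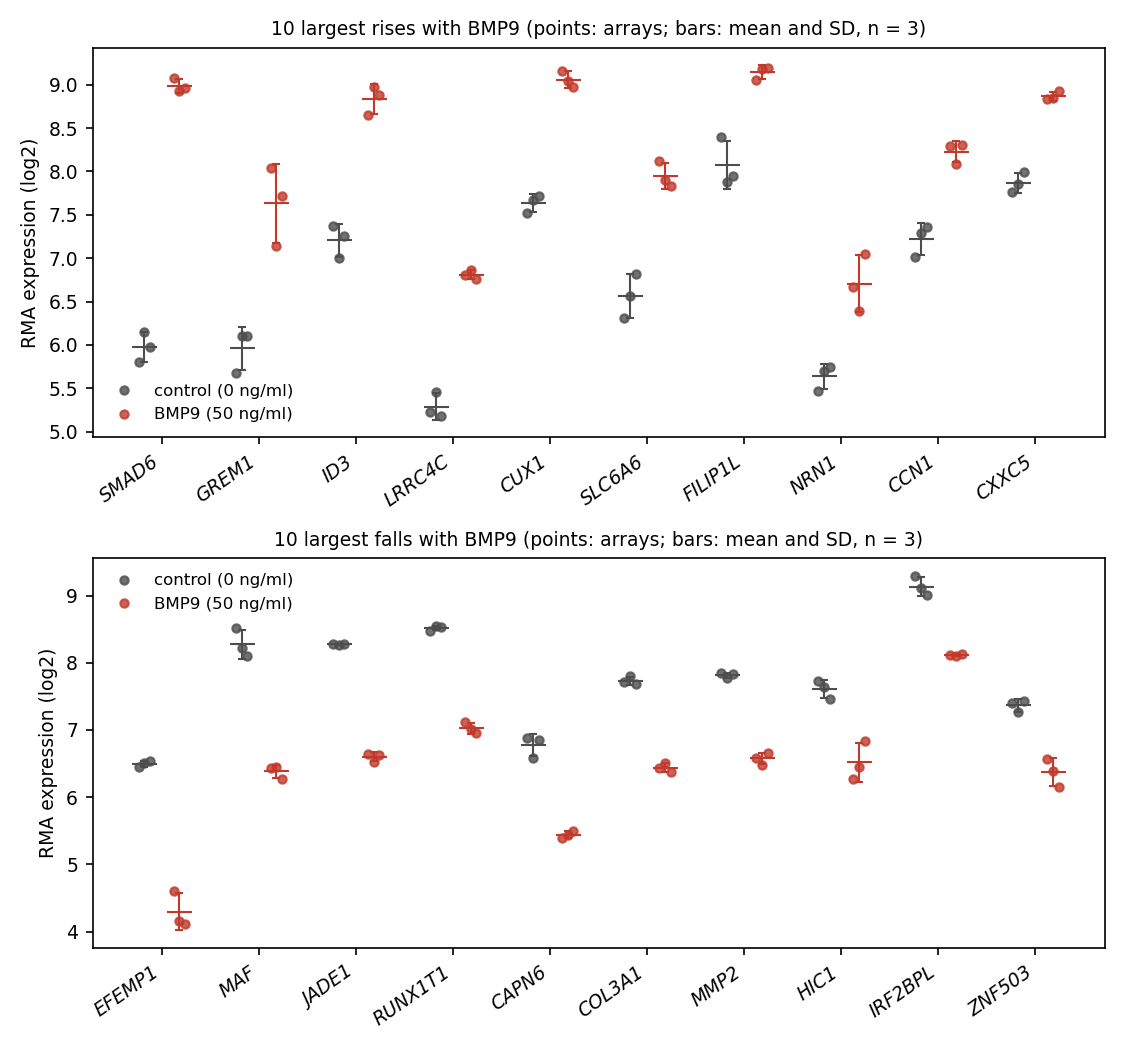
RMA expression (log2) of the 10 genes with the largest rise and the 10 with the largest fall under the naming rule; points are arrays, bars are mean and SD (n = 3 per group). In each gene all 3 BMP9 arrays (red) lie on the same side of all 3 control arrays (grey).

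The list of BMP-SMAD1/5/9 direct targets was higher with BMP9, with a mean log2 difference of 0.44 over 24 measured genes (limma camera adjusted p = 3.30e-07), of which 5 rose and 0 fell, or 7 and 0 adjusted over the list alone. With an estimated correlation the list's call was lost (adjusted p = 0.0979), and over its alternatives the adjusted p ranged from 7.09e-35 to 0.0979. The risen members were SMAD6, GREM1, ID3, ID2 and ID4. ID2 rose by 1.21 (SE 0.23, limma adjusted p = 0.0492), from a control mean of 4.60 ± 0.60 to 5.81 ± 0.067 (SD, n = 3), a call lost when control replicate 2 or any single BMP9 replicate was left out and when probe sets were averaged or combined by Simes' method. ID4 rose by 0.99 (SE 0.093), a call that ended when probe sets with shared probes were left out or all probe sets averaged. HEY1 (0.39) and SNAI2 (0.29) passed over the list alone and, over all genes, with either scaling to control probe sets. Hybridisation scaling called 4502 of 18132 genes higher and poly-A scaling 17425, so passing there says little about a single gene. SMAD7, the other inhibitory SMAD, differed by 0.21 (SE 0.096, limma adjusted p = 0.390) in the chosen probe set. Another SMAD7 probe set went from 3.61 ± 0.20 to 4.33 ± 0.26 (SD, n = 3), a difference of 0.72 that did not pass over all probe sets (limma adjusted p = 0.0603), with no overlap between the groups, and the remaining one differed by 0.21. HAMP, the hepcidin gene, differed by -0.14 (limma adjusted p = 0.510), a difference that turned positive with poly-A scaling.

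The probe set that the rule chose for ID1, a classical BMP target, differed by 0.14 (SE 0.095, limma adjusted p = 0.582), from 5.50 ± 0.12 to 5.64 ± 0.14 (SD, n = 3). Another ID1 probe set went from 2.80 ± 0.42 in control to 6.01 ± 0.22 with BMP9 (SD, n = 3), a rise of 3.21 (SE 0.18, limma adjusted p = 1.55e-05 over all probe sets). The remaining ID1 probe set differed by 0.32 (limma adjusted p = 0.386). ID1 passed when its probe sets were averaged or combined by Simes' method.

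**Figure D3:**
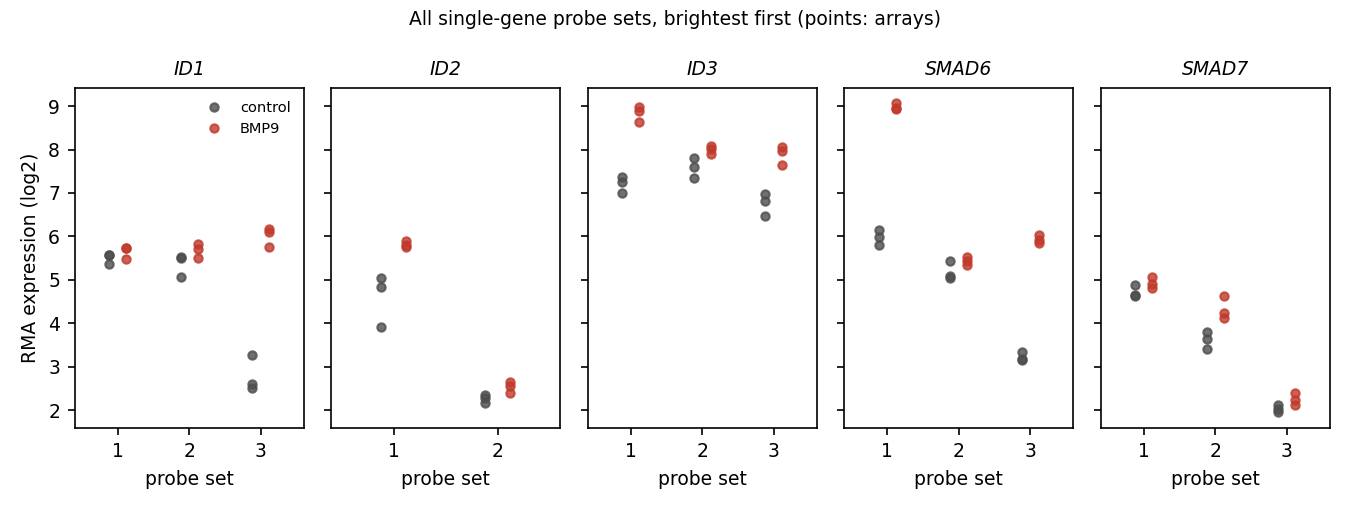
RMA expression (log2) on each array for every single-gene probe set of ID1, ID2, ID3, SMAD6 and SMAD7, numbered from the highest mean; grey points are control arrays and red points BMP9 arrays (3 each). ID1's dimmest probe set rises by 3.21 while its brighter ones differ by 0.14 and 0.32, and SMAD6 rises in the brightest and the dimmest of its 3.

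The receptors and transducers of BMP9 were not called as a list (14 measured, 0 rose and 2 fell in both adjustments, over all genes and adjusted over the list alone, limma camera adjusted p = 0.973). The receptor gene ACVR2A fell by 0.66 (SE 0.091) and the co-receptor gene RGMB by 0.57 (SE 0.091), which turned positive with poly-A scaling. ACVRL1 differed by -0.027, BMPR2 by 0.048 and ENG by 0.038, none of which passed, and ACVRL1 turned positive with poly-A scaling. The ligand list was not called (16 measured, 0 rose, 1 fell, the same adjusted over the list alone, limma camera adjusted p = 0.550). INHBB, an activin subunit, fell by 0.91 (SE 0.13), GDF2 differed by -0.042 (positive with poly-A scaling) and TGFB1 by 0.14. BMPR2 stood at 3.76 ± 0.10 and GDF2 at 3.39 ± 0.076 in control (SD, n = 3), and without detection calls neither is known to lie above background. TGF-beta-SMAD2/3 targets held 17 measured genes with 0 past the threshold over all genes, and 2 higher and 2 lower adjusted over the list alone (limma camera adjusted p = 0.683).

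Matrix proteases and their inhibitors were lower with BMP9 as a list (17 measured, mean -0.17, limma camera adjusted p = 0.0226). The call was lost with an estimated correlation (adjusted p = 0.412). That estimate was -0.036, below the preset 0.01, so correlation between the list's members did not end the call there. The call was also lost when probe sets were averaged (adjusted p = 0.248) or each entered on its own (adjusted p = 0.289). A minimum mean log2 value of 5 (adjusted p = 0.0673) and each gene's own variance in each group (adjusted p = 0.159) ended it too, as did leaving out control replicate 2 (adjusted p = 0.224). Over the list's alternatives the adjusted p ranged from 8.26e-05 to 0.412. MMP2, the membrane-bound activator gene MMP14 (-0.58) and the urokinase gene PLAU (-0.42) fell and 0 rose; adjusted over the list alone, ADAMTS1 (-0.43) joined them and CTSK (0.31), named after its value was seen, was higher. MMP14, PLAU and ADAMTS1 turned positive with poly-A scaling, and the list's mean turned positive with both control scalings (0.036 and 0.44). Relative to other genes, the list was still called lower under both scalings. MMP14 and PLAU lost their calls whichever array was left out and when probe sets were averaged or combined by Simes' method. ADAMTS1 passed over all genes under 4 of its alternatives. TIMP1, an inhibitor of these proteases, differed by 0.055 (limma adjusted p = 0.867).

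Collagens were not called as a list (18 measured, mean -0.12, limma camera adjusted p = 0.212). They were called under 6 of 20 alternatives (adjusted p 0.00558 to 0.630 over all 20). These were averaged probe sets, no probe sets with shared probes, no control replicate 3, no BMP9 replicate 1 and either control scaling. Under the scalings, which add a shift to every gene, the mean turned positive (0.077 and 0.48). The list was still called lower relative to other genes there. COL3A1 and COL16A1 (-0.45) fell and 0 rose, the same adjusted over the list alone, with COL16A1 losing its call with hybridisation scaling and turning positive under poly-A scaling. COL1A1 stood at 9.73 ± 0.16 in control and 9.79 ± 0.10 with BMP9, and COL1A2 at 7.54 ± 0.11 and 7.64 ± 0.033 (SD, n = 3), differences of 0.052 and 0.10 that did not pass (95% intervals -0.16 to 0.27 and -0.076 to 0.28). Collagen maturation and cross-linking held 16 measured genes and 0 past the threshold, with PLOD2 (-0.37, positive with poly-A scaling) lower adjusted over the list alone (limma camera adjusted p = 0.550). In non-collagen matrix 1 of 22 measured genes fell, the laminin gene LAMA4 (-0.53, positive with poly-A scaling), and adjusted over the list alone 3 were higher and 4 lower (limma camera adjusted p = 0.550).

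Stellate cell state was measured by 3 lists, none of them called. Of 17 myofibroblast contractile genes ACTG2, a smooth muscle actin gene, rose by 0.44 and 0 fell, with VIM (-0.37, positive with poly-A scaling) lower adjusted over the list alone (limma camera adjusted p = 0.814). VIM passed over all genes under 3 of its alternatives. ACTA2, whose product is the usual marker of activated stellate cells, was at 3.90 ± 0.082 in control and 4.04 ± 0.15 with BMP9 (SD, n = 3, limma adjusted p = 0.577). Its other probe sets were dimmer still, and none is known to lie above background without detection calls. The lack of a call therefore does not show that ACTA2 was unchanged. Of 16 quiescent stellate cell genes 0 passed, and HGF (0.62), which passed over all genes under 7 of its alternatives, was higher adjusted over the list alone (limma camera adjusted p = 0.265). Of 16 activation receptors 1 fell, PDGFRA, a receptor for platelet-derived growth factor, by 1.03 (SE 0.15), and adjusted over the list alone 1 was higher and 2 were lower (limma camera adjusted p = 0.429). The PDGFRA call ended without BMP9 replicate 1 or 3 and when probe sets were averaged.

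**Figure D4:**
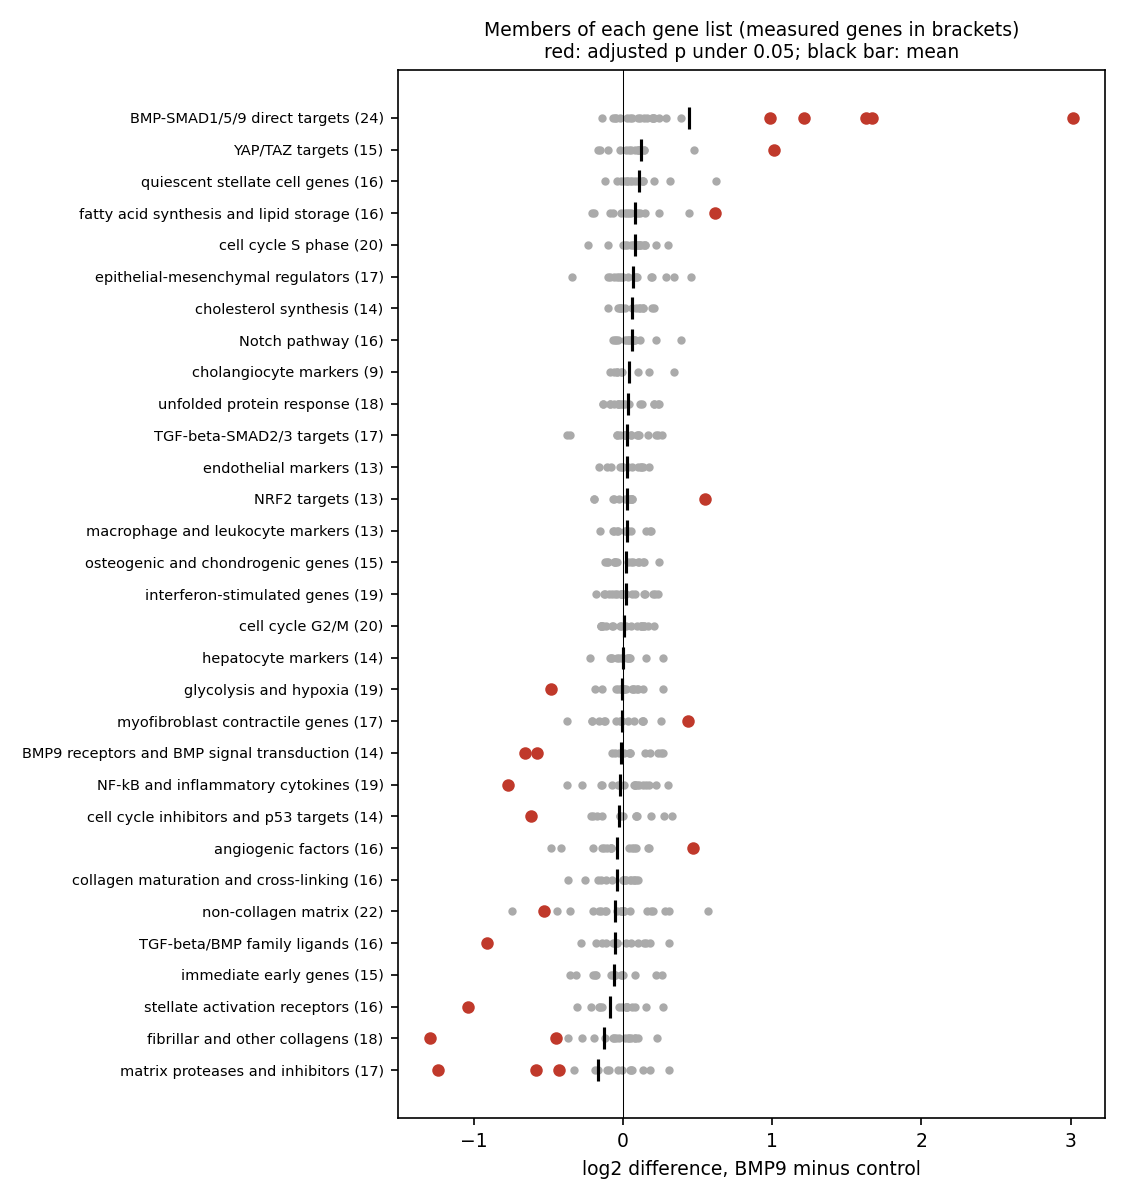
Log2 difference between BMP9 and control for each measured member of the 31 gene lists; red points have a limma adjusted p under 0.05 over all genes, grey points do not, and the black bar is the list's mean. The list of BMP-SMAD1/5/9 direct targets has a mean of 0.44 and matrix proteases and inhibitors one of -0.17. The latter mean turns positive when arrays are scaled to either kind of control probe set, while the list is still called lower relative to other genes.

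Single members passed in several lists that were not called by limma's camera. CCN1 was the only YAP/TAZ target to rise (15 measured, 2 higher adjusted over the list alone, adjusted p = 0.347). The chemokine gene CCL5 fell by 0.77 among 19 NF-kB and inflammatory genes (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.949). The growth arrest gene GADD45A fell by 0.62 among 14 cell cycle inhibitors and p53 targets (1 lower adjusted over the list alone, adjusted p = 0.785). The acetyl-CoA synthetase gene ACSS2 rose by 0.62 among 16 genes of fatty acid synthesis and lipid storage (2 higher adjusted over the list alone, adjusted p = 0.429). The glucose transporter gene SLC2A1 fell by 0.48, turning positive with poly-A scaling, among 19 genes of glycolysis and hypoxia (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.949). NQO1, a quinone reductase gene, rose by 0.55 among 13 NRF2 targets (1 higher adjusted over the list alone, adjusted p = 0.968), and the ephrin gene EFNB2 rose by 0.47 among 16 angiogenic factors (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.550). The calls of ACTG2, SLC2A1 and EFNB2 were lost whichever array was left out, those of ACVR2A, RGMB, INHBB, COL16A1, LAMA4, GADD45A, ACSS2 and NQO1 without any of 3 to 5 single arrays, and that of CCL5 when probe sets were averaged. Averaging also ended the calls of ACTG2, SLC2A1, EFNB2, RGMB, LAMA4, ACSS2 and NQO1, Simes' method those of ACTG2, SLC2A1, LAMA4 and NQO1, and poly-A scaling those of ACVR2A, INHBB, CCL5 and GADD45A. Leaving out probe sets with shared probes ended that of ACTG2.

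No member passed over all genes in the other proliferation, stress and signalling lists, and limma's camera called none of them. S phase had 20 measured genes, 18 of them with a positive difference (adjusted p = 0.248), and G2/M had 20, with 10 in each direction (adjusted p = 0.972). The adjusted p was 0.489 for the Notch pathway (16 measured), 0.949 for osteogenic and chondrogenic genes (15), 0.929 for interferon-stimulated genes (19), 0.429 for cholesterol synthesis (14), 0.785 for the unfolded protein response (18), 0.296 for immediate early genes (15) and 0.489 for epithelial-mesenchymal regulators (17). Adjusted over the list alone, PCNA (0.30) was higher in S phase, JUNB (0.26) was higher and JUN (-0.36) and SPRY2 (-0.31), both positive with poly-A scaling, lower among immediate early genes, and among epithelial-mesenchymal regulators 3 were higher and 1 lower; the other 6 of these lists had 0. JUN passed over all genes under 3 of its alternatives. By fry, which does not compare a list with other genes, S phase (adjusted p = 0.00759) and cholesterol synthesis (adjusted p = 0.00478) were also higher.

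Markers of other liver cells gave 0 genes past the threshold: 14 hepatocyte markers (limma camera adjusted p = 0.949), 13 endothelial markers (0.909), 13 macrophage and leukocyte markers (0.949) and 9 cholangiocyte markers (0.814). Adjusted over the list alone the count was 0 in the first 3 and 1 in the last, EPCAM, at 1.92 ± 0.02 in control and 2.26 ± 0.14 with BMP9 (SD, n = 3). The median and the mean or the test had opposite signs in 9 lists: BMP9 receptors, collagen maturation, stellate activation receptors, NF-kB and inflammatory genes, interferon-stimulated genes, glycolysis and hypoxia, the unfolded protein response, and hepatocyte and cholangiocyte markers.

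The array's control probe sets were compared between the same groups of arrays. The poly-A controls averaged 6.30 ± 0.059 on control arrays and 5.70 ± 0.24 on BMP9 arrays, and the hybridisation controls 10.41 ± 0.045 and 10.21 ± 0.069 (SD, n = 3). In both, all BMP9 arrays lay below all control arrays (exact permutation p = 0.1, the smallest possible). Ribosomal RNA probe sets differed by -0.17 (exact permutation p = 0.3). The 5′ minus 3′ difference of ACTB was 4.19 ± 0.10 in control and 4.37 ± 0.074 with BMP9 (SD, n = 3, exact permutation p = 0.1), and that of GAPDH was 1.27 ± 0.11 and 1.43 ± 0.11 (SD, n = 3, exact permutation p = 0.2). In both genes the 5′ probe set read above the 3′ one, while in the poly-A control dap it read below (-1.91 ± 0.053 and -1.93 ± 0.12, SD, n = 3). Probe sets thus differ in how they read, and these differences are a weak guide to RNA quality. Background probe sets averaged from 1.67 to 10.0 depending on their GC content, so the level of a probe set is not a measure of abundance relative to other probe sets. The choice of the probe set with the highest mean and the minimum of 6 in the naming rule compare such levels and share this limit.

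**Figure D5:**
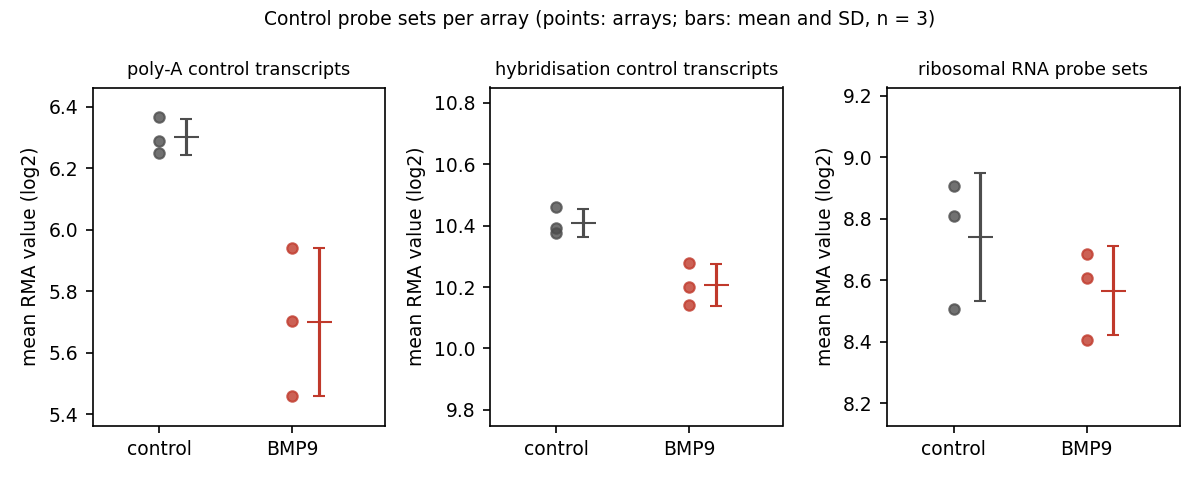
Mean RMA value (log2) of the poly-A control, hybridisation control and ribosomal RNA probe sets on each array, with mean and SD beside the points (n = 3 per group) and the same vertical span in each panel. The poly-A controls are lower by 0.60 and the hybridisation controls by 0.20 on the BMP9 arrays, without overlap, and ribosomal RNA overlaps.

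With 1 array left out, 17 to 24 genes were higher and 37 to 54 lower, so both counts dropped by more than 1.5 times whichever of the 6 arrays was left out. Fewer arrays also mean less power, so calls lost in this way do not show that an array was unusual. Testing each gene with its own variance in each group, which drops both limma's shared prior and the assumption of equal variances, left 0 calls after adjustment, with 1518 genes at an unadjusted p under 0.05 (2334 in limma).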

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

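The 3 tests of the control probe sets were chosen after their values were seen, and the comparison of probe sets outside the gene table was not among the planned ones. Probe sets that carry several gene symbols or none were left out of the gene comparison and tested in limma among all probe sets, with adjustment over all of them. Of 4305 such probe sets, 8 were higher and 6 lower with BMP9 at an adjusted p under 0.05, which drew attention as a signal in data that the report does not use. They are given as counts, since no single gene can be named for them.

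The splits of the 6 arrays into 3 and 3 are 10 in number, too few for a share under 0.05. The real split gave 42 genes higher, 82 lower and 2 lists, and the highest of the other splits gave 0 for each; 1 split, the real one, gave as many in each case.

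The poly-A controls were 0.60 lower and the hybridisation controls 0.20 lower on the BMP9 arrays, a pattern to follow up because it sets how the 42 rises and 82 falls are read. The shift of the hybridisation controls was smaller at higher values, from -0.34 for bioB (8.10 in control) to -0.089 for cre (13.27, where the arrays' highest value is 13.62), so both kinds were compared at a similar value, which does not match their background. There the poly-A control dap shifted by -0.25 (SE 0.17) relative to bioB, with overlap between the groups, and a single offset per array cannot be told apart from a larger shift of the poly-A controls. Averaged over all probe sets of each kind, the poly-A minus hybridisation difference shifted by -0.40, without overlap (exact permutation p = 0.1), but at unlike values. Less poly-A control mix in the BMP9 samples stays open for the poly-A controls: the shifts of its 4 transcripts spanned 0.28, against a standard error of up to 0.23 for a single shift. It would not by itself lower the hybridisation controls, which are supplied already labelled. More messenger RNA per total RNA with BMP9 may contribute, as a hypothesis that stays open: it would lower ribosomal RNA like the poly-A controls, and the 6 ribosomal RNA probe sets, a weak reference since they are labelled only by chance priming, shifted by -0.41 to 0.26 (the last higher on all 3 BMP9 arrays), all of them above dap, 3 by more than 2 standard errors, which goes against it, and 3 by less, the lowest by 0.18 (SE 0.14).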

How the results depend on the processing

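The 4 alternatives named in the methods as chosen after seeing the data are the scalings to control probe sets, Simes' method and the removal of shared-probe suffixes; the others were planned. Against 42 genes higher, 82 lower and 2 lists, a minimum mean log2 value of 5 gave 102, 165 and 1 list. A minimum of 7 gave 97 and 150 genes, and an intensity trend with a robust prior gave 103 and 182. With the minimum of 7, neither of the 2 called lists kept the 5 genes needed for a test. Of the lists that could still be tested there, 0 were called. Every probe set on its own gave 66 and 136 probe sets and 1 list, and a 1.5-fold minimum gave 20 and 45 by construction. Welch's test gave 0 and 0 genes, with 1518 at an unadjusted p under 0.05 (2334 in limma), and 1 list. Camera with an estimated correlation called 0 lists and fry 4. Scaling to hybridisation controls gave 4502 higher and 75 lower, and scaling to poly-A controls 17425 and 15. With the replicate number as a block, limma called 27 higher and 67 lower. The labels state no pairing by number. Deviations of same-numbered arrays correlated at 0.0038, 0.046 and -0.021, and not every array correlated best with its own number. No pairing showed in these values, but 3 arrays per group are too few to exclude it. Without 1 array, 17 (without BMP9 replicate 2) to 24 (without control replicate 2) genes were higher, 37 to 54 lower at the same arrays, and 1 to 3 lists were called. Poly-A scaling turned GDF2 (0.56), ACVRL1 (0.57), HAMP (0.46), RGMB (0.028), COL16A1 (0.15), MMP14 (0.021), PLAU (0.18), LAMA4 (0.072), SLC2A1 (0.12), FZD2 (0.012), TCF4 (0.036), MEIS1 (0.055) and ITGBL1's chosen probe set (0.41) positive, because it adds the same shift to every gene. Quantile normalisation, median centring, averaged probe sets, Simes' method and the removal of shared-probe suffixes kept both counts within 1.5 times and shared 124, 122, 60, 95 and 97 genes with the 124. With the suffixes removed, only 115 of the 124 could be tested. Over 83 named genes and the number of lists called under each alternative, 1217 values stayed the same, 235 were weaker, 59 stronger and 13 reversed. For a gene, the same means that it kept its side of the threshold, weaker that it lost it and stronger that it gained it. The number of called lists was judged by a change of 1.5 times instead. Among the genes' values, 22 more changed sign while past the threshold in neither setting. The causes of these changes were not tested where none is given. Without detection calls, signal over background is known only from the background probe sets, and small changes of dim probe sets are the least certain.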

Other observations

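The genes of the first 2 paragraphs and those named for a probe set that the rule did not choose were picked after their values were seen; the tests of shared probes and gene length were written down before their results. The iron exporter gene SLC40A1 fell with BMP9 by 1.33 (SE 0.20), from 4.64 ± 0.51 to 3.31 ± 0.038, and the ferroxidase gene CP by 1.12 (SE 0.082), from 5.61 ± 0.076 to 4.48 ± 0.099 (SD, n = 3, limma adjusted p = 0.0138 and 0.000106). The SLC40A1 call ended without control replicate 1 or any BMP9 replicate. The angiotensin receptor gene AGTR2 fell by 0.94, the lysophosphatidic acid receptor gene LPAR4 by 0.82, IGF1 by 0.66 and the Wnt receptor gene FZD2 by 0.59, the last turning positive with poly-A scaling, which ended the calls of the other 3. The IGF1 and LPAR4 calls also ended when probe sets were averaged. The growth factor receptor gene FGFR2 rose by 0.82 (SE 0.13) and the neurotrophin gene BDNF by 0.84 (SE 0.074, limma adjusted p = 0.000547); the FGFR2 call ended without any of 5 single arrays, all but control replicate 2, and when probe sets were averaged or combined by Simes' method, and the LPAR4 call ended without any of 4 arrays. The BDNF call ended when its probe sets were averaged (0.31), and 2 of its 5 probe sets had a negative difference, of -0.13 each.

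OSR2 (-1.27), ZBTB18 (-0.92), NFAT5 (-0.73), HIF1A (-0.61), TCF4 (-0.56) and MEIS1 (-0.55) fell too (limma adjusted p 0.000892 to 0.0221). TCF4 and MEIS1 turned positive with poly-A scaling and lost their calls without any of 5 single arrays and when probe sets were averaged. The calls of ZBTB18, NFAT5 and HIF1A ended with poly-A scaling, those of ZBTB18 and NFAT5 without probe sets with shared probes, and that of NFAT5 when probe sets were averaged. The clock gene BMAL1 rose by 0.68 (SE 0.082, limma adjusted p = 0.00431), from 7.05 ± 0.057 to 7.73 ± 0.11 (SD, n = 3). NFIL3, another regulator of the clock, rose by 0.42, a call lost whichever array was left out. The creatine transporter gene SLC6A8 rose by 0.71 and the kinase gene SGK1 by 0.70 (SE 0.09 and 0.078); both calls ended without probe sets with shared probes, and that of SLC6A8 also when probe sets were averaged. No list of these genes was tested.

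Probe sets of a gene often disagreed: of 138 genes with several probe sets and at least 1 called, 122 had a silent probe set, and in 36 genes, ID1 among them, the probe set that the rule chose was silent. Silent means not called and with a difference of the opposite sign to, or under 50% of, that of the gene's probe set with the smallest p. No minimum level was asked for, so a silent probe set may be one that does not lie above background. In probe sets that the rule did not choose, the homeobox gene DLX2 rose by 1.76 (limma adjusted p = 0.00299 over all probe sets), while RGMA, which encodes a BMP co-receptor, fell by 1.45 (9.74e-05), ITGBL1 by 1.64 (0.00687) and TGFBR3, the betaglycan gene, by 0.84 (0.0234). The chosen probe set of DLX2 was called higher with either control scaling, and that of ITGBL1 with the poly-A one. Over all genes, RGMA was called lower under 6 of its alternatives, averaged probe sets and Simes' method among them. Averaging and Simes' method also called DLX2 higher and TGFBR3 lower, and Simes' method called ITGBL1 lower. Probes shared with other transcripts were not set apart: suffixes that mark them were on 30.9% of the 317 silent and 30.8% of called probe sets (Fisher's exact p = 1), which leaves that explanation open for single genes. No biological explanation, such as transcript forms, was tested.

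Genes that fell with BMP9 were long. The median gene length of the 82 was 38.3 kb, against 23.0 kb (95% of lists between 15.3 and 33.4 kb) in 10000 lists matched on mean log2 value, at percentile 99.56. A larger number of probe sets per long gene was checked with lists matched also on broad classes of that number. The median stayed at percentile 98.77, so differences between these classes did not account for the length. Genes with many probe sets shared a single class, so the match is too coarse to settle this explanation. The 42 risen genes were longer still, at a median of 71.0 kb against 22.8 kb in matched lists, so length goes with change in either direction and may be a property of BMP9-responsive genes or of regulated genes in general, as a hypothesis. This hypothesis was not tested, nor was any other biological explanation.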
